A study of Mus musculus with 4 samples.

How the data were processed

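RNA had been extracted with a column kit from sorted BC cells of mouse prostate, and indexed libraries had been made from polyA RNA with the Ovation Solo system. Each of the 2 groups, Pten and Pten_p65KO, holds 2 libraries. Per the labels, the authors used FastQC, Trimmomatic, STAR 2.7.5a, Picard and HTSeq 0.11.1 on the GRCm38 (mm10) genome. The gene annotation and the strand setting are not stated in the labels. The deposited table holds 1 value per gene and library, a score that the authors made by scaling the gene counts of each library to a total of about 20000000 and rounding up to a whole number. This scaling is not described in the labels and was read from the name of the table and from its values.

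Low values take only steps of a constant size per library, so the reads behind them were recovered with the step that, after rounding up, gives the largest share of values. That share was 99.9%, 99.9%, 99.9% and 99.8% of the values above 0, each required to match exactly. Depth was 6813458 and 6729061 reads in Pten and 7261327 and 7460998 reads in Pten_p65KO. A count of 0 allows up to 3 reads, which is 8.81, 8.92, 8.26 and 8.04 in the deposited unit for the 4 libraries in that order, or 7.59 as the mean of the Pten_p65KO libraries after composition scaling. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Recovered reads were used for depth, for the weights behind the composition factors, for the filters on low values, for the voom alternative and for the simulation.

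The comparison was Pten_p65KO against Pten with all 4 libraries. Before the data were examined, a model for raw counts had been chosen, with limma on log2(value + 1) to take its place for normalized values. The table holds scaled values, so limma 3.58.1 in R 4.3.3 was used, with a mean-variance trend, a pseudocount of 1, two-sided tests and Benjamini-Hochberg adjusted p under 0.05. Genes were kept with the equivalent of at least 10 reads in at least 2 libraries and at least 15 reads in all. Values were divided by trimmed-mean composition factors of 0.945, 0.917, 1.06 and 1.08, computed with 30% of the log ratios and 5% of the average levels trimmed at each end. Gene positions were taken from a GENCODE annotation of GRCm38, in which 49412 of 49671 gene identifiers (99.5%) were found.

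Fixed at the same time were 32 gene lists, the rule for named genes and most alternatives. The lists are those that the results name, from the targeted genes and NF-kB targets to markers of other cell types and ribosomal proteins. Lists with at least 3 tested genes, 30 in all, were tested with camera (limma) at a preset correlation of 0.01, with camera at a correlation estimated per list and with fry, and p-values were adjusted over the lists. Calls of the members were also adjusted over the list alone. The rule names Rela, Pten, Krt5, Krt14, Trp63, Krt8, Krt18, Nkx3-1 and Mki67. It adds the 10 largest rises and 10 largest falls among called genes with an average log2 CPM of at least 3 and no overlap between groups, leaving out predicted genes. It adds up to 4 genes per list with the smallest unadjusted p. Genes named outside the rule are said to have been chosen after their values were seen. Of the targeted genes Rela and Pten, 1 fell and 1 rose.

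The fit was tested on simulated data with 17261 tested genes, with 200 genes changed and a dispersion of 0.0183 taken from the replicates. Its adjusted threshold was stricter than in the data, where far more genes were called. Of 50 genes changed 1.5-fold 6 were called, of 50 changed 2-fold 44, and all 50 changed 4-fold and all 50 changed 8-fold. There were 14 calls of unchanged genes, 8.54% of all calls. Of simulated lists, 5 of 5 shifted and 0 of 20 unchanged lists were called by camera. The simulated genes were drawn independently with a shared dispersion. The simulation therefore does not check lists of correlated genes or genes with a wider spread. Alternatives were another scaling, library totals alone, voom on the recovered reads, no filter or a stricter one, a replicate block, other thresholds and each library left out in turn. Added after the data had been examined were limma without the trend, pseudocounts of 3 and 10, rRNA-like genes left out of the totals with no composition factor, and markers of immune, luminal and seminal vesicle cells left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The Wald test on raw counts that had been planned as an alternative was left out because the table holds no raw counts.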

Results

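Transcript levels were measured by bulk RNA-seq in BC cells that had been isolated from mouse prostate by fluorescence-activated cell sorting. The cells were taken 6 weeks after deletion of Pten, the gene of a lipid phosphatase that restrains PI3K signalling. The 4 libraries fell into 2 groups of 2. The Pten group carried the Pten deletion, and the Pten_p65KO group carried it together with a knockout of p65, the NF-kB subunit encoded by Rela. The Pten libraries held 6813458 and 6729061 reads and the Pten_p65KO libraries 7261327 and 7460998 reads, as recovered from the step between low deposited values. In the deposited unit, reads scaled to 20000000 per library, 1 read was worth 2.94, 2.97, 2.75 and 2.68. Between 26633 and 27770 genes had at least 1 read in a library, and 17361 genes were tested. Values are given in the deposited unit as mean ± SD with n = 2. Fold changes are on the log2(value + 1) scale after composition scaling, with their standard error (SE). The labels do not say whether the libraries of a group came from separate mice, so the p-values measure the spread between these libraries only.

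The comparison addressed what p65, and with it innate immune signalling, contributes to the state of BC cells after Pten loss. No group without the Pten deletion was included, so whether an effect of p65 loss depends on Pten loss cannot be told. In Pten_p65KO, genes of the NF-kB pathway, chemokines and cytokines, and interferon-stimulated genes were lower, with median log2 fold changes of -1.70, -2.72 and -2.26. Markers of proximal luminal progenitors were lower as well, at a median of -1.42. These 4 lists passed camera with a preset correlation but not with an estimated one (adjusted p = 0.39, 0.374, 0.374 and 0.39 with an estimated correlation). Immune cell markers were lower in the same libraries, at a median of -1.22 (camera adjusted p = 4.21e-06, and adjusted p = 0.374 with an estimated correlation). Nkx3-1, a homeobox regulator of luminal identity, and Txnip, a FOXO target, rose 6.90-fold and 6.62-fold. Pten transcripts were also higher in Pten_p65KO (log2 fold change 0.65, SE 0.12), and the values do not check the Pten allele. Differences between the groups therefore cannot be credited to the loss of p65 alone.

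Rela itself (ENSMUSG00000024927, chromosome 19, 5637483 to 5648130, GRCm38) fell 3.63-fold, from 4497 ± 319.6 in Pten to 1446.5 ± 316 in Pten_p65KO. Its log2 fold change was -1.86 (SE 0.18), with a limma adjusted p of 8.61e-04, in the direction its label gives. Reads of Rela were left in both knockout libraries, at 1670 and 1223. Pten (ENSMUSG00000013663, chromosome 19, 32757497 to 32826160) was at 2466 and 2503 in the Pten libraries and 4358 and 4625 in the Pten_p65KO libraries. Its log2 fold change was 0.65 (SE 0.12), with a limma adjusted p of 0.0103. Values summed over a whole gene do not separate reads of deleted exons from the rest, so they do not check the Pten allele and check the Rela allele only in part. The Pten call was lost without Pten_p65KO replicate 1 and without replicate 2, where its log2 fold change was 0.67 and 0.62.

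Of the 17361 genes, 4381 (25.2%) passed an adjusted p of 0.05 in the limma fit, 2053 higher and 2328 lower in Pten_p65KO. The larger changes were mostly falls, with 588 genes lower by 4-fold or more and 177 higher by as much. Both libraries of one group lay above both of the other for 67.2% of tested genes, where chance gives 33.3%. Correlations across genes, which are not independent replicates, were 0.967 and 0.974 within the groups and 0.894 to 0.905 between them. The split of calls depended on the scaling. With library totals alone 3586 genes were higher and 1690 lower, and the median log2 fold change of all tested genes was 0.24, against 0.03 with composition scaling. The count of calls was 2548 without Pten_p65KO replicate 1 and 2464 without replicate 2, 904 with no filter on low values and 2630 without the mean-variance trend.

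**Figure D1:**
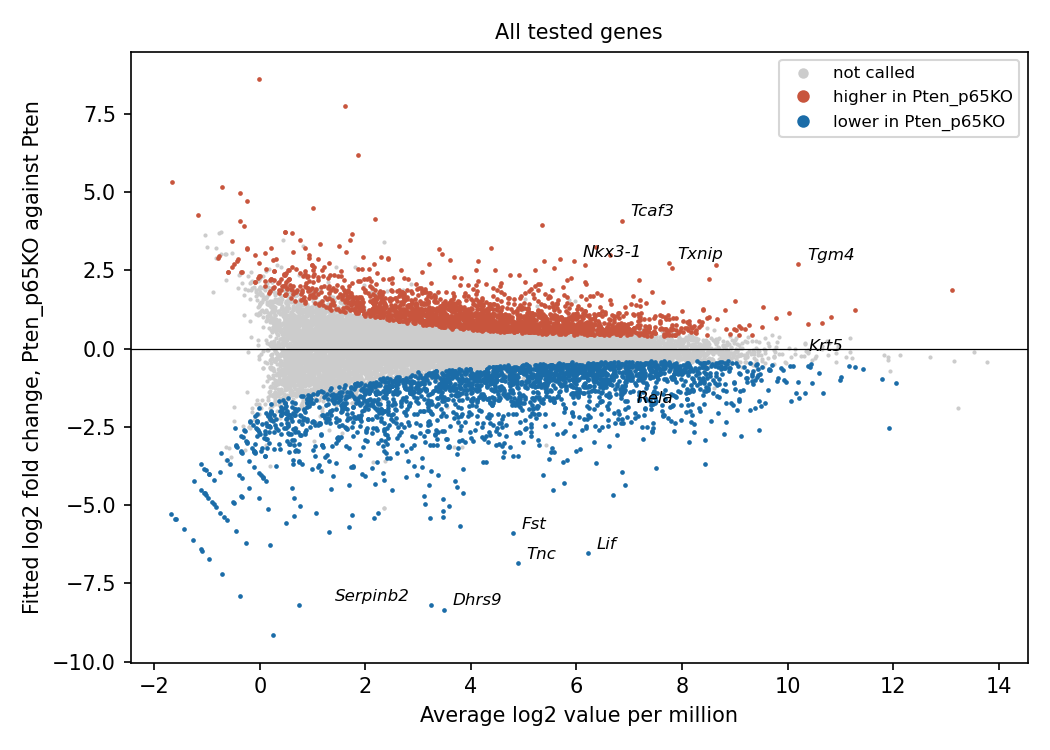
Fitted log2 fold change of Pten_p65KO against Pten (vertical axis) against the average level as log2 CPM (horizontal axis) for the 17361 tested genes, each a point. The 2053 genes called higher are red, the 2328 called lower are blue and the others grey, with Dhrs9 at -8.34 and Tgm4 at 2.69.

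The genes of the NF-kB pathway and its feedback targets fell with Rela. Of 20 tested members 16 fell, 1 rose and 3 were not called, against 17 lower and 1 higher when adjusted over the list alone. The list had a camera adjusted p of 1.64e-07, and adjusted p = 0.39 with an estimated correlation. Tnfaip3, which encodes the deubiquitinase A20 that restrains NF-kB signalling, fell 15.4-fold, from 8506.5 ± 252 in Pten to 636.5 ± 0.707 in Pten_p65KO (limma adjusted p = 4.27e-05). The inhibitor gene Nfkbia fell 4.63-fold (log2 fold change -2.21, SE 0.14), and the subunit genes Nfkb1 and Nfkb2 fell 3.69-fold and 4.02-fold. Ikbke, an IKK-related kinase gene named after its values were seen, rose at 0.58 (SE 0.17). Its call was lost with median-of-ratios scaling (limma adjusted p = 0.0572), without Pten replicate 1 (0.115), and without Pten_p65KO replicate 1 (0.304) or 2 (0.0895). Among 11 NF-kB survival genes 3 fell, 1 rose and 7 were not called, against 3 lower and 2 higher when adjusted over the list alone. Survival genes had a camera adjusted p of 0.344, and adjusted p = 0.699 with an estimated correlation. Ier3 (-1.56), Gadd45b (-1.89) and Birc3 (-1.55) fell. Bcl2, an inhibitor of apoptosis, rose at 0.63, a call lost without either Pten_p65KO library (limma adjusted p = 0.0993 and 0.0817). Without Pten replicate 1, 5 survival genes were lower, and with library totals alone 3 were higher.

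Secreted inflammatory signals fell as well. Of 26 tested chemokines and cytokines 20 fell, none rose and 6 were not called in the limma fit, with the same counts when adjusted over the list alone. Chemokines and cytokines had a camera adjusted p of 1.10e-10, and adjusted p = 0.374 with an estimated correlation. Setting the members at 0 to their bounds of -3.781 and -3.535 left the median at -2.72, since both bounds lie below it. Lif, a cytokine of the IL-6 family, fell 93.2-fold, from 14894 ± 8975 in Pten to 176.5 ± 85.6 in Pten_p65KO (log2 fold change -6.54 (SE 0.47), limma adjusted p = 3.29e-04). Its log2 fold change ran from -7.22 to -5.86 with each library left out in turn. The neutrophil chemoattractants Cxcl1 and Cxcl2 fell 12.3-fold and 9.97-fold, and Il1rn, the interleukin-1 receptor antagonist, fell 27.9-fold. Cxcl3 and Ccl20, named after their values were seen, had no read in either Pten_p65KO library. Their Pten values were 89 and 105 for Cxcl3 and 89 and 75 for Ccl20, so that they were at least 13.8-fold and 11.6-fold lower, with a floor of 3 reads per library that covers counting error only.

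Immune cell markers, listed as a check of the sort, were lower in the same libraries. Of 18 tested 10 fell, none rose and 8 were not called, against 14 lower and 0 higher when adjusted over the list alone. Immune cell markers had a camera adjusted p of 4.21e-06, and adjusted p = 0.374 with an estimated correlation. Their levels were low in the Pten libraries, with means of 273.5 for Itgam, 448.5 for Cd3e, 256 for Laptm5 and 139 for Itgb2. These 4 genes fell, with log2 fold changes of -2.52, -1.75, -1.67 and -2.54.

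Interferon-stimulated genes, which carry antiviral functions, were the list with the smallest camera p-value of the 30 tested. Of 39 tested members 36 fell, none rose and 3 were not called, against 38 lower and 0 higher when adjusted over the list alone. Interferon-stimulated genes had a camera adjusted p of 6.71e-18, and adjusted p = 0.374 with an estimated correlation. The immune cell markers fell in the same libraries, at a median of -1.22 against -2.26 for this list. Oasl2, of the oligoadenylate synthetase family, fell from 1648 ± 48.1 in Pten to 300.5 ± 14.8 in Pten_p65KO, and Usp18, Zbp1 and Ifit3 fell 8.41-fold, 20.4-fold and 37.8-fold. The log2 fold change of Ifit3 ran from -5.84 to -4.65 with each library left out in turn. Trim25, Irgm2 and Ifit2, the members not called over all genes, were at -0.50, -0.88 and -0.09 and were named after their values were seen. Trim25 and Irgm2 passed without Pten replicate 1 (limma adjusted p = 0.0143 and 0.0339). Ifit2 was at 0.12 with library totals alone, 0.10 with rRNA-like genes left out of the totals and 0.028 without Pten replicate 2.

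In the list of MHC class I presentation 10 of 19 members fell, none rose and 9 were not called, against 13 lower and 0 higher when adjusted over the list alone. Class I presentation genes had a camera adjusted p of 2.14e-07, and adjusted p = 0.374 with an estimated correlation. Among them fell the heavy chain genes H2-D1 (-2.03), H2-Q4 (-2.37) and H2-K1 (-1.80) and Nlrc5 (-3.18), which encodes the class I transactivator. H2 genes are close paralogs that vary between mouse strains, so their counts are uncertain. The immune cell markers also fell in these libraries, at a median of -1.22. Of 8 class II presentation genes 3 fell, 1 rose and 4 were not called, with the same counts when adjusted over the list alone. Class II presentation genes had a camera adjusted p of 0.286, and adjusted p = 0.622 with an estimated correlation. They passed under 1 of 15 alternative settings (camera adjusted p between 0.0409 and 0.664). Cd74 (-1.01), H2-DMb2 (-2.61) and H2-Aa (-0.88) fell, and H2-Eb1 rose, at 12 and 12 in the Pten libraries and 182 and 124 in the Pten_p65KO libraries. The call of H2-DMb2 was lost without Pten replicate 1 (limma adjusted p = 0.0607). The call of H2-Aa was lost without Pten replicate 2 (limma adjusted p = 0.0786), without Pten_p65KO replicate 1 (0.147), and with library totals alone (0.062) or with rRNA-like genes left out of them (0.0526).

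Among 29 innate sensors and adaptors 10 fell, 2 rose and 17 were not called, against 10 lower and 4 higher when adjusted over the list alone. Sensors and adaptors had a camera adjusted p of 0.0573, and adjusted p = 0.39 with an estimated correlation. They passed under 5 of 15 alternative settings (camera adjusted p between 0.0386 and 0.121). The lipopolysaccharide co-receptor gene Cd14 fell at -2.15 (SE 0.19), the receptor genes Tlr2 and Nod2 at -2.89 (SE 0.29) and -2.95 (SE 0.35), and the inflammatory caspase gene Casp4 at -1.71 (SE 0.14). The myeloid cell marker genes Itgam and Itgb2 fell in the same libraries, at -2.52 (SE 0.28) and -2.54 (SE 0.40). The members that rose, named after their values were seen, were Mavs (1.11) and Il1rap (1.01). Mavs was not called without Pten_p65KO replicate 1 (limma adjusted p = 0.0618), and 4 members were higher with library totals alone and without Pten replicate 2. Of 16 complement, acute-phase and antimicrobial genes 9 fell, none rose and 7 were not called, against 10 lower and 1 higher when adjusted over the list alone. Complement, acute-phase and antimicrobial genes had a camera adjusted p of 0.0013, and adjusted p = 0.374 with an estimated correlation. Lcn2, which encodes an iron-scavenging antimicrobial protein, fell from 2978.5 ± 513 in Pten to 1067 ± 189.5 in Pten_p65KO. Pigr, Ltf and Pglyrp1 fell as well, at -3.10, -4.43 and -2.60, with ranges over the left-out libraries of -3.77 to -2.44 for Pigr, -5.65 to -3.22 for Ltf and -3.47 to -1.74 for Pglyrp1.

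**Figure D2:**
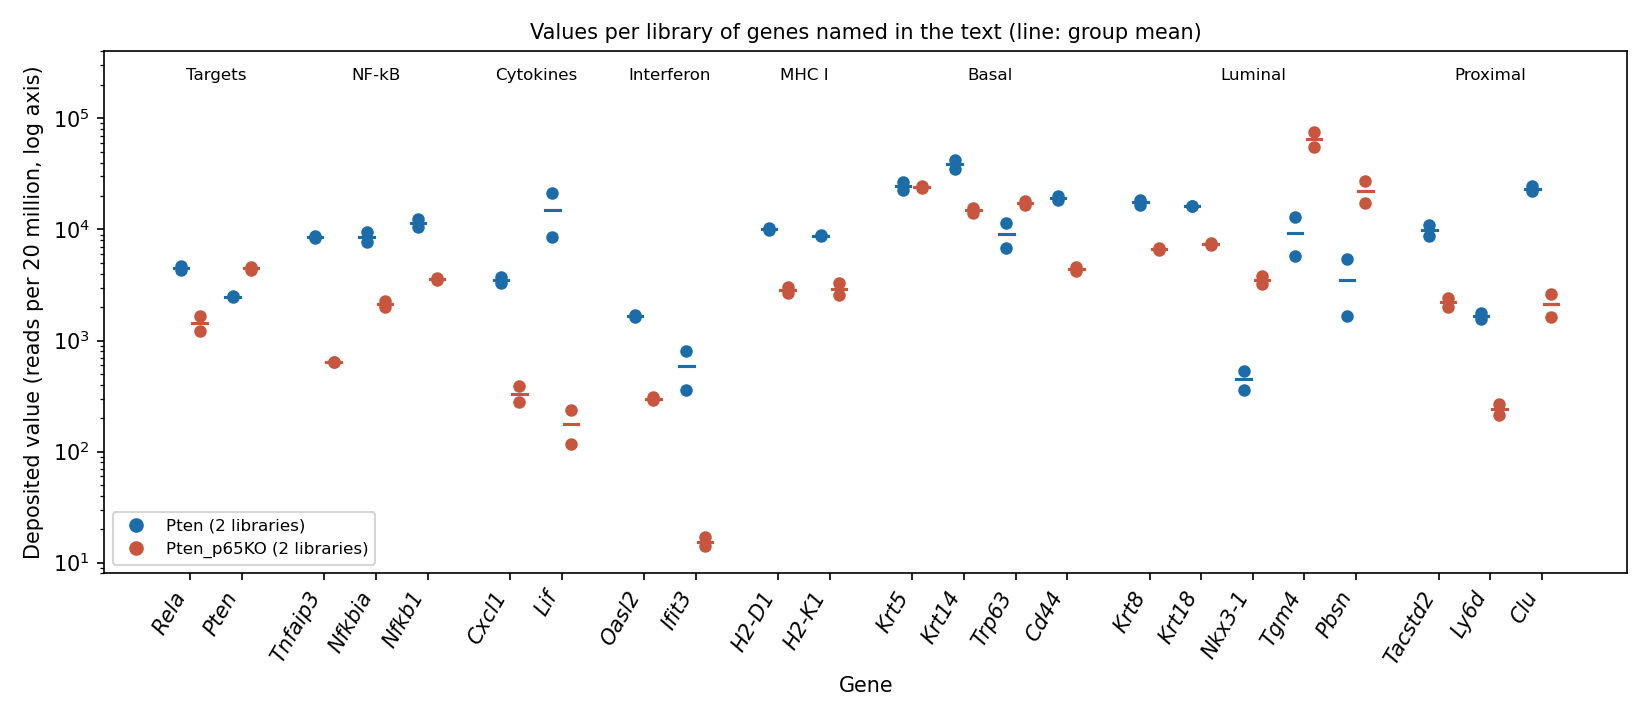
Deposited values (reads scaled to 20000000 per library, log axis) of 23 named genes (horizontal axis) in each library, blue for the 2 Pten and red for the 2 Pten_p65KO libraries, with a line at each group mean. Tnfaip3 was at 8328 and 8685 against 637 and 636, Krt5 overlapped between the groups at 26472 and 22637 against 24566 and 23831, and Tgm4 was at 5815 and 12897 against 54883 and 76044.

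Epithelial identity genes moved in several directions. Krt5, a keratin of prostate basal cells, was at 24554 ± 2712 in Pten and 24198 ± 519.7 in Pten_p65KO. Its log2 fold change of -0.22 (SE 0.14) did not pass (limma adjusted p = 0.271). Krt14, its usual partner, fell 3.01-fold, from 38872 ± 5020.5 in Pten to 14862 ± 1066 in Pten_p65KO (limma adjusted p = 7.63e-04). Trp63, the gene of the transcription factor p63 that maintains basal cells, rose at 0.76 (SE 0.23), with a limma adjusted p of 0.046. The Trp63 call was lost with median-of-ratios scaling (limma adjusted p = 0.0501), without Pten replicate 2 (0.0738) and without Pten_p65KO replicate 1 (0.104). Of 22 basal markers 12 fell, 3 rose and 7 were not called, against 14 lower and 3 higher when adjusted over the list alone. Basal markers had a camera adjusted p of 3.64e-04, and adjusted p = 0.374 with an estimated correlation. Cd44 (-2.33), Krt17 (-2.59) and Col17a1 (-1.67) were among the members that fell. Besides Trp63, Jag2 (0.85) and Dlk2 (0.99), named after their values were seen, rose. Jag2 was not called without Pten_p65KO replicate 1 (limma adjusted p = 0.0643).

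Luminal markers split. Of 21 tested 12 rose, 5 fell and 4 were not called, with the same counts when adjusted over the list alone. Luminal markers had a camera adjusted p of 0.0699, and adjusted p = 0.774 with an estimated correlation. The list passed under 7 of 14 alternative settings (camera adjusted p between 0.0027 and 0.232), with a rise in each. Nkx3-1 rose from 448.5 ± 122 in Pten to 3521 ± 397 in Pten_p65KO (limma adjusted p = 3.86e-04), and Azgp1, which encodes a secreted zinc-binding glycoprotein, rose as well, at 3 and 15 in the Pten libraries and 601 and 730 in the Pten_p65KO libraries. The secretory genes Tgm4 and Pbsn, named after their values were seen, rose 6.46-fold and 6.30-fold to means of 65464 and 22272. Both were higher in replicate 2 of each group than in replicate 1. Tgm4 was at 12897 against 5815 in Pten and 76044 against 54883 in Pten_p65KO, and Pbsn at 5407 against 1650 and 27198 against 17347. Over the left-out libraries, the log2 fold changes ran from 5.15 to 7.22 for Azgp1, 2.10 to 3.29 for Tgm4 and 1.78 to 3.53 for Pbsn. The secretory gene 9530053A07Rik, also named after its values were seen, took 0.328% and 0.578% of the reads in the Pten libraries and 1.64% and 2.05% in the Pten_p65KO libraries. The luminal keratin genes Krt8 and Krt18 fell 3.05-fold and 2.53-fold, with limma adjusted p of 4.76e-04 and 6.70e-04. Krt8 fell from 17589 ± 1287 in Pten to 6647.5 ± 162 in Pten_p65KO, and Krt18 from 16200 ± 149 in Pten to 7393.5 ± 114 in Pten_p65KO. The other members that fell, named after their values were seen, were the adhesion and junction genes Cdh1 (-1.41) and Cldn3 (-1.52) and the surface marker gene Cd24a (-0.86). The Cldn3 call was lost with library totals alone (limma adjusted p = 0.0533), and its log2 fold change was between -2.26 and -0.78 over the left-out libraries.

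Markers of proximal luminal progenitors, a population near the urethra, fell as a list. Of 19 tested 15 fell, none rose and 4 were not called, against 17 lower and 0 higher when adjusted over the list alone. Proximal progenitor markers had a camera adjusted p of 1.64e-07, and adjusted p = 0.39 with an estimated correlation. Clu, which encodes a secreted chaperone, fell 13.0-fold, from 23176 ± 1699 in Pten to 2118 ± 686 in Pten_p65KO. The surface protein genes Ly6d, Tacstd2 and Ly6a fell 7.99-fold, 5.14-fold and 3.80-fold. Of 13 squamous and stress keratins and envelope genes 10 fell, none rose and 3 were not called, with the same counts when adjusted over the list alone. Squamous and stress keratins had a camera adjusted p of 7.66e-05, and adjusted p = 0.39 with an estimated correlation. Krt16 (-4.51), Krt6a (-3.57), Krt80 (-2.92) and Sfn (-1.83) were among them. Among 19 stem and plasticity factors 13 fell, 2 rose and 4 were not called, against 14 lower and 3 higher when adjusted over the list alone. Stem and plasticity factors had a camera adjusted p of 2.56e-04, and adjusted p = 0.39 with an estimated correlation. The transcription factor genes Klf5 and Runx1 fell 6.37-fold and 3.40-fold, and the chromatin protein gene Hmga1 fell 5.29-fold. The members that rose, named after their values were seen, were Sox2 (1.09) and Sox11 (1.59). Sox11 was not called without Pten replicate 2 (limma adjusted p = 0.0548) or Pten_p65KO replicate 2 (0.144).

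Targets of FOXO transcription factors, which PI3K signalling holds inactive, passed camera with a rise at the preset correlation only. Pten transcripts were higher in the same libraries, at 2466 and 2503 in Pten and 4358 and 4625 in Pten_p65KO. The values do not check the Pten allele, so the rise of FOXO targets cannot be credited to the loss of p65 alone. FOXO targets had a camera adjusted p of 0.0197, and adjusted p = 0.699 with an estimated correlation. The list did not pass fry (adjusted p = 0.088). Among the 30 lists it was the only one to pass with a rise under all libraries and the settings used throughout, where luminal markers had a camera adjusted p of 0.0699. Of 18 tested 9 rose, 2 fell and 7 were not called, against 10 higher and 2 lower when adjusted over the list alone. The list did not pass without Pten replicate 2 (camera adjusted p = 0.083) or Pten_p65KO replicate 1 (0.0579). Txnip, a regulator of glucose uptake and redox state, rose from 1562.5 ± 145 in Pten to 11916 ± 105 in Pten_p65KO (limma adjusted p = 1.19e-04), and the stress-response gene Sesn1 rose 4.22-fold, whereas Bcl6 (-1.68) and Trib1 (-1.10) fell. In the list of AP-1 and dissociation response 8 of 22 rose, 2 fell and 12 were not called, against 8 higher and 4 lower when adjusted over the list alone. AP-1 and dissociation genes had a camera adjusted p of 0.26, and adjusted p = 0.774 with an estimated correlation. The immediate-early genes Btg2 (1.34), Ier2 (1.25) and Egr1 (1.24), which tissue dissociation also induces, rose, and the AP-1 subunit gene Fosl1 fell 6.25-fold. Of 16 p53 and senescence genes 5 fell, 1 rose and 10 were not called, with the same counts when adjusted over the list alone. Genes of p53 and senescence had a camera adjusted p of 0.0081, and adjusted p = 0.374 with an estimated correlation. The cell cycle inhibitor gene Cdkn1a fell from 4483.5 ± 480.1 in Pten to 1081.5 ± 71.4 in Pten_p65KO, and the death receptor gene Tnfrsf10b fell at -1.95. Ccng1, named after its values were seen, rose at 0.63, a call lost without either Pten_p65KO library (limma adjusted p = 0.0594 and 0.0842).

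Of 28 proliferation genes 3 fell, none rose and 25 were not called, with the same counts when adjusted over the list alone. Proliferation genes had a camera adjusted p of 0.0049, and adjusted p = 0.764 with an estimated correlation. They did not pass fry (adjusted p = 0.356). The list did not pass without Pten replicate 1 or Pten_p65KO replicate 2 (camera adjusted p = 0.19 and 0.117). Top2a, Ube2c and Ccnb2, genes of mitosis, fell 2.73-fold, 2.63-fold and 2.15-fold. Without Pten_p65KO replicate 2 only Top2a was called, since Ube2c and Ccnb2 had limma adjusted p of 0.053 and 0.0917. Ccnb2 was also lost without Pten replicate 1 (limma adjusted p = 0.0674), where 1 member was higher. There were 5 members lower without Pten replicate 2 and 7 without Pten_p65KO replicate 1. Mki67, a marker of cycling cells, was at 1072 and 830 in the Pten libraries and 959 and 464 in the Pten_p65KO libraries (log2 fold change -0.71 (SE 0.33), limma adjusted p = 0.153). Mki67 passed without Pten_p65KO replicate 1 (-1.25, limma adjusted p = 0.0057) and was at -0.16 without Pten_p65KO replicate 2 (0.722). In the list of epithelial-mesenchymal transition 7 of 17 fell, 2 rose and 8 were not called, against 8 lower and 2 higher when adjusted over the list alone. Genes of this transition had a camera adjusted p of 0.0564, and adjusted p = 0.39 with an estimated correlation. They passed under 6 of 15 alternative settings (camera adjusted p between 0.0204 and 0.141). The matrix genes Tnc (-6.84) and Fn1 (-3.82) fell, as did Itga5 (-3.16) and Vim (-1.22). A single member was higher without Pten_p65KO replicate 1.

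The 4 remaining pathway lists did not pass camera and held calls both ways. Of 19 androgen response genes 5 rose, 5 fell and 9 were not called, against 6 and 6 when adjusted over the list alone. Androgen response genes had a camera adjusted p of 0.86, and adjusted p = 0.923 with an estimated correlation. Their median and mean differed in sign, at -0.05 and 0.11. Tsc22d3 rose at 1.97 beside Nkx3-1, and Ndrg1 (-2.39) and Aldh1a3 (-2.63) fell, while 3 members were lower without Pten_p65KO replicate 1. Of 14 YAP targets 6 fell, 2 rose and 6 were not called, with the same counts when adjusted over the list alone. YAP targets had a camera adjusted p of 0.223, and adjusted p = 0.718 with an estimated correlation. F3 (-2.91), Areg (-3.90) and Tead1 (-1.08) fell and Ajuba rose (1.10), and 1 member was higher without Pten_p65KO replicate 1. In the Notch pathway 5 of 14 fell, 1 rose and 8 were not called, with the same counts when adjusted over the list alone. Notch pathway genes had a camera adjusted p of 0.494, and adjusted p = 0.828 with an estimated correlation. Sox4 (-1.55), Dll1 (-1.20) and Hes1 (-1.01) fell and Jag2 rose. Without Pten_p65KO replicate 2, 3 members were lower, without Pten replicate 1, 3 were higher, and without Pten_p65KO replicate 1 none was higher. Of 15 TGF-beta and BMP targets 6 fell, 4 rose and 5 were not called, against 6 lower and 7 higher when adjusted over the list alone. TGF-beta and BMP targets had a camera adjusted p of 0.881, and adjusted p = 0.923 with an estimated correlation. Ltbp1 (-2.13), Tgfb2 (-1.40) and Skil (-1.31) fell and Id3 rose (1.13). Without Pten_p65KO replicate 2, 3 members were lower, and without Pten replicate 1, 7 were higher.

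**Figure D3:**
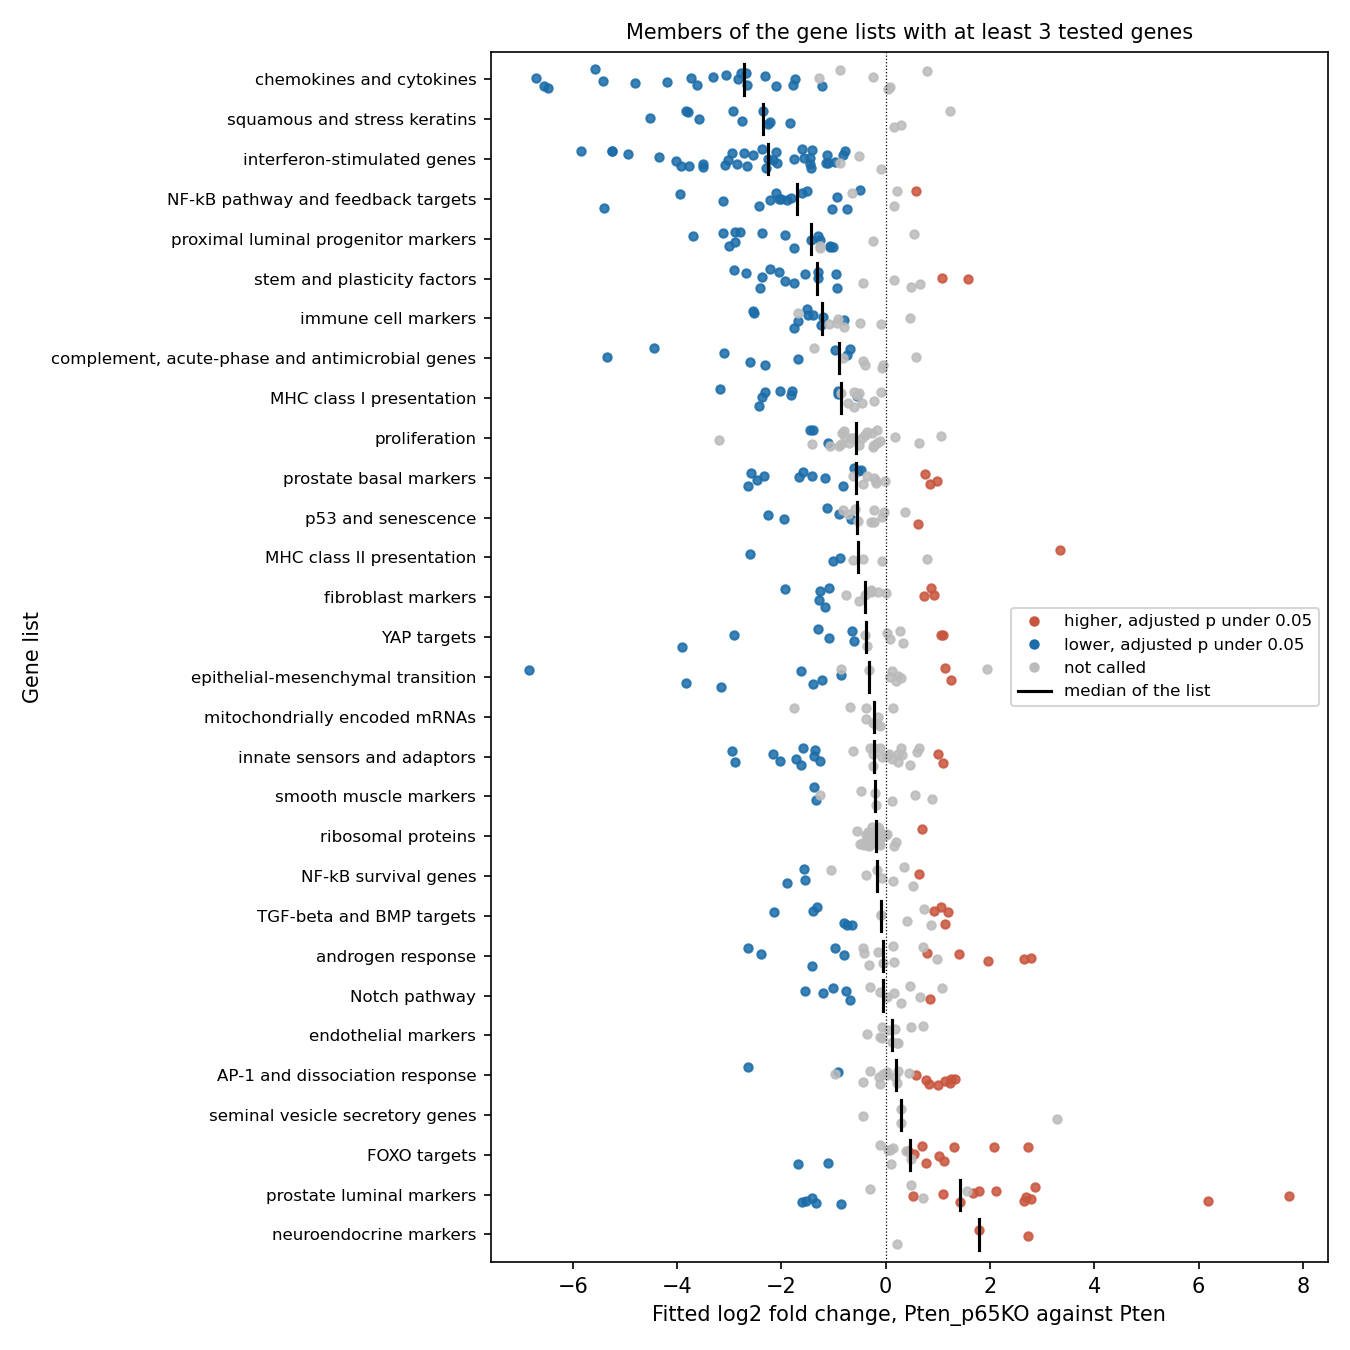
Fitted log2 fold change of Pten_p65KO against Pten (horizontal axis) for every tested member of the 30 gene lists with at least 3 tested genes (vertical axis), each point a gene, red or blue where called higher or lower and grey otherwise, with a line at the list's median. The medians run from -2.72 for chemokines and cytokines to 1.78 for neuroendocrine markers, and luminal markers spread to both sides.

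By the naming rule, which leaves out genes of low average level, the largest fall was that of Dhrs9, a dehydrogenase gene (ENSMUSG00000027068, chromosome 2, 69380445 to 69404533). It fell 323-fold, from 3922 ± 1499 in Pten to 13 ± 5.66 in Pten_p65KO (log2 fold change -8.34 (SE 0.38), limma adjusted p = 1.19e-04). The Pten_p65KO values of Dhrs9 were 17 and 9. The value in replicate 2 is close to the floor of 3 reads, 8.04 in that library, so this fold is of uncertain size. Serpinb2, a gene of an inhibitor of plasminogen activators, fell 290.0-fold from a mean of 2993.5, to 6 and 19 in the Pten_p65KO libraries. The value of 6 in replicate 1 lies below the floor of 3 reads, 8.26 in that library, so the size of the fold is uncertain. The matrix glycoprotein gene Tnc and the activin antagonist gene Fst fell 114-fold and 59.6-fold. Tnip3 (-5.41), Calcb (-5.39), Stx11 (-5.20), Slc14a1 (-5.03) and Rps3a3 (-5.68) were in the same group, as was Lif. The largest rise was that of Tcaf3, at 185 and 1481 in the Pten libraries and 9040 and 11758 in the Pten_p65KO libraries (log2 fold change 4.09 (SE 0.81), limma adjusted p = 0.0127). The renin gene Ren1 and the growth factor gene Egf rose 9.40-fold and 6.96-fold, and Fgl1, Msmb and Hvcn1 rose 8.08-fold, 7.26-fold and 7.13-fold, with Fam198b at 2.81. Over the left-out libraries, the log2 fold changes ran from 2.57 to 5.61 for Tcaf3, 2.13 to 4.34 for Ren1, 1.81 to 3.91 for Msmb and 1.91 to 3.68 for Egf. Among the falls they ran from -6.42 to -4.39 for Tnip3, -8.91 to -7.45 for Serpinb2 and -6.40 to -4.95 for Rps3a3. Rpl29 rose 15.5-fold, at 218 and 167 in the Pten libraries and 3427 and 3440 in the Pten_p65KO libraries. Rpl29 and Rps3a3, annotated as a processed pseudogene, share sequence with near-identical ribosomal copies, so their counts are uncertain. Among the largest rises, Tcaf3, Ren1, Fgl1, Msmb, Fam198b, Egf and Nkx3-1 were higher in replicate 2 of each group, as Tgm4 and Pbsn were. Rpl29, Hvcn1 and Txnip were not higher in replicate 2 of both groups.

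Markers of the other cell types that a prostate sort can hold were tested as well. Of 15 fibroblast markers 5 fell, 3 rose and 7 were not called, with the same counts when adjusted over the list alone. Fibroblast markers had a camera adjusted p of 0.0906, and adjusted p = 0.39 with an estimated correlation. The collagen genes Col1a1 (-1.93) and Col3a1 (-1.17) fell, and Pdgfrb (0.93), Pdgfra (0.87) and C7 (0.73), named after their values were seen, rose. None of these 3 was called without Pten_p65KO replicate 1, where their limma adjusted p were 0.0656, 0.105 and 0.134, and 1 was called without replicate 2. Of 9 smooth muscle markers Smtn (-1.34) and Tagln (-1.37) fell and 7 were not called, against 3 lower and 1 higher when adjusted over the list alone, and 1 was higher without Pten replicate 1. Smooth muscle markers had a camera adjusted p of 0.289, and adjusted p = 0.718 with an estimated correlation. None of 11 endothelial markers was called by limma, over all genes as when adjusted over the list alone, and 1, Esam, had an unadjusted p under 0.05. Endothelial markers had a camera adjusted p of 0.592, and adjusted p = 0.774 with an estimated correlation. Of 3 neuroendocrine markers Chgb and Syp rose, as they did when adjusted over the list alone, from at most 12 in each Pten library. Neuroendocrine markers had a camera adjusted p of 0.0906, and adjusted p = 0.39 with an estimated correlation. They passed under 1 of 14 alternative settings (camera adjusted p between 0.0186 and 0.379). Neither was called without either Pten_p65KO library (limma adjusted p between 0.0572 and 0.208), Syp was lost without Pten replicate 1 (0.0783) and Chgb without Pten replicate 2 (0.055). Syp was also lost with median-of-ratios scaling (limma adjusted p = 0.0522) and voom (0.0537).

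Seminal vesicle secretory genes, a sign of fluid or cells of the neighbouring gland, were high in replicate 2 of both groups. Svs2 was at 0 and 2839 in the Pten libraries and 0 and 1858 in the Pten_p65KO libraries. None of the 4 tested was called by limma over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and 2 were higher without Pten_p65KO replicate 1. Seminal vesicle genes had a camera adjusted p of 0.86, and adjusted p = 0.923 with an estimated correlation. A single erythroid gene, Alas2, was tested and was not called, at 0.30 with all libraries and -0.33 without Pten replicate 1. None of 10 mitochondrially encoded mRNAs was called by limma over all genes or adjusted over the list alone, 1 (mt-Co3) had an unadjusted p under 0.05, and 1 was lower without Pten_p65KO replicate 2. Mitochondrial mRNAs had a camera adjusted p of 0.125, and adjusted p = 0.774 with an estimated correlation. They passed under 1 of 15 alternative settings (camera adjusted p between 0.0044 and 0.804). Of 32 ribosomal protein genes Rps18 alone rose (0.69), none fell, and none was called when adjusted over the list alone. Ribosomal protein genes had a camera adjusted p of 0.0581, and adjusted p = 0.787 with an estimated correlation. They passed under 3 of 15 alternative settings (camera adjusted p between 2.86e-04 and 0.758). Without Pten replicate 2, 12 of them were lower, and Rps18 was not called without Pten_p65KO replicate 1 (limma adjusted p = 0.104).

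None of the 13 lists that passed camera with the preset correlation passed with a correlation estimated per list. That setting rests on 2 residual degrees of freedom. In all, 14 lists passed fry, which tests whether the genes of a list move, on balance, one way. Among the 13, FOXO targets and proliferation genes did not pass fry (adjusted p = 0.088 and 0.356). Sensors and adaptors, epithelial-mesenchymal transition and fibroblast markers passed fry (adjusted p = 0.0206, 0.0206 and 0.0471) but not camera. Of the 156 genes named, 51 lost their call when no filter on low values was used and 30 without the mean-variance trend.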

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

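The fits without the trend, with pseudocounts of 3 and 10, with rRNA-like genes left out of the totals and with markers of other cell types left out were chosen after the data had been seen, and the other alternatives were planned. Rela was called lower under all 15 alternatives to its fit, at -2.10 to -1.61. The 4381 calls became 904 (269 higher, 635 lower) with no filter on low values, 2630 (1155, 1475) without the trend and 2468 (983, 1485) with a fold of at least 2 required as well, where the last drops smaller changes by construction. The causes of the other losses were not tested. Genes higher became 3586 with library totals only and 3435 with rRNA-like genes left out of those totals, both without composition factors, and the median of all genes became 0.24 and 0.22. Leaving out each library in turn gave 2464 to 4323 calls, 842 to 2113 higher and 1595 to 2210 lower, with fewer samples and the lone library of a group assumed to vary like the other group. Camera with an estimated correlation called 0 lists in place of 13. The p53 and senescence list, estimated at -0.022 against the preset 0.01, went from an unadjusted camera p of 0.0032 to 0.0874. With an estimated correlation camera rests on the 2 residual degrees of freedom of the fit. Its smallest unadjusted p over the lists was then 0.067, so the lack of calls cannot be put down to correlation alone. Signs turned for 3 genes that were not called. Ifit2 was at 0.12 with library totals only and 0.10 with rRNA-like genes left out. Over the left-out libraries Ifit2 ran from -0.21 to 0.028, Svs2 from -6.24 to 5.39 and Alas2 from -0.33 to 0.93, and the cause was not tested. Of 156 named genes 51 lost their call with no filter, 30 without the trend, 18 without Pten_p65KO replicate 1, 12 without Pten_p65KO replicate 2, and at most 5 under any other alternative. The labels do not say that a replicate number marks a shared animal or batch, and deviations from the group means correlated at 0.18, where 2 pairs are too few to settle whether the numbers pair the libraries. A replicate block gave 5316 calls, of which 4377 were shared. With it luminal markers passed camera (adjusted p = 0.0211), Mki67, Trim25 and Irgm2 were called (limma adjusted p = 0.0251, 0.0392 and 0.0209), and Syp was not (0.0525). Of the proliferation genes 10 were then lower and 1 higher. The planned DESeq2 test was not run because the table holds no raw counts. At depths of 6729061 to 7460998 reads, 1 read was worth 2.68 to 2.97 units, and genes below the filter were not tested.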

Other observations

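All groups and tests in this part were chosen after the values had been seen. Adjusting over the 5 gene groups does not correct for that choice, so their p-values are descriptive. Genes of plasminogen activation, a protease system at the cell surface, were lower in Pten_p65KO, with 5 of 6 tested genes lower, 0 higher and 1 not called. These genes had a camera adjusted p of 1.19e-04 over 5 groups chosen after the values were seen, and adjusted p = 0.137 with an estimated correlation. The receptor gene Plaur fell 25.6-fold, from 9772 ± 1892 in Pten to 443.5 ± 118 in Pten_p65KO, and the activator genes Plau and Plat fell 10.7-fold and 6.69-fold. The inhibitor genes Serpinb2 and Serpine1 fell as well, at -8.18 and -1.62, so the group did not lose activators alone. Of 12 genes of the IL-6 family and its STAT3 response 8 fell, 0 rose and 4 were not called. The IL-6 group had a camera adjusted p of 8.74e-05 over 5 groups chosen after the values were seen, and adjusted p = 0.137 with an estimated correlation. The kinase gene Pim1, a STAT3 target, fell 7.88-fold, Il6 fell 6.34-fold, and Stat3 itself fell 1.76-fold. The STAT3 feedback gene Socs3 was not called (-0.44, limma adjusted p = 0.0644), nor were the receptor genes Il6st, Lifr and Il6ra.

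Ligands of the EGF receptor family parted. Of 10 tested 7 fell, 2 rose and 1 was not called. The ligands had a camera adjusted p of 0.0035 over 5 groups chosen after the values were seen, and adjusted p = 0.168 with an estimated correlation. Areg fell at -3.90, and Ereg and Nrg1 fell 9.79-fold and 4.46-fold, whereas Egf and Nrg2 rose 6.96-fold and 4.22-fold. Egf was at 162 and 538 in Pten and 1967 and 2877 in Pten_p65KO. It was thus higher in replicate 2 of each group, as the luminal secretory genes Tgm4 and Pbsn were. Nrg2 did not share this, at 441 and 277 in Pten and 1656 and 1754 in Pten_p65KO. Of 14 integrin subunit genes 6 fell, 1 rose and 7 were not called. Integrin subunits had a camera adjusted p of 0.008 over 5 groups chosen after the values were seen, and adjusted p = 0.168 with an estimated correlation. Itga2 and Itgb6 fell 12.5-fold and 5.16-fold, and Itgb8 rose at 0.61, a call lost without either Pten_p65KO library (limma adjusted p = 0.0643 and 0.0827). Of 10 genes of neuropeptides, neuronal vesicles and neurofilaments 8 rose and 1, Calcb, fell. Neuronal genes had a camera adjusted p of 0.0012 over 5 groups chosen after the values were seen, and adjusted p = 0.223 with an estimated correlation. Vip was at 0 and 9 in the Pten libraries and 182 and 46 in the Pten_p65KO libraries and Nefl at 12 and 3 in the Pten libraries and 204 and 57 in the Pten_p65KO libraries. Pten_p65KO replicate 1 was also above replicate 2 for Syt4 (174 against 84), Sv2c (171 against 76), Snap25 (163 against 70) and Nefm (240 against 51). Nsg2 was at 39 against 30, and Syt10 went the other way, at 39 against 59. The calls of Vip, Nefl and Snap25 were lost without Pten_p65KO replicate 1 (limma adjusted p = 0.112, 0.0853 and 0.105), and that of Nefl with voom (0.0653).

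The NF-kB pathway, chemokine and interferon lists fell together with immune cell markers, which may mean that fewer immune cells entered the Pten_p65KO sorts. A loss of such cells alone would lower no transcript further than the cells themselves. Of 20, 26 and 39 members, 2, 8 and 8 fell further than every one of the 18 immune cell markers, by more than 2 standard errors of the difference. These are the members that fell most, and the markers ran from -2.54 to 0.47, so that a cell type without a marker may have fallen further. Fewer immune cells and the loss of p65 in the BC cells, which the design names, therefore cannot be told apart for these lists. For the sensor genes Cd14, Tlr2 and Nod2, the class I and II lists and the IL-6 group this was not tested.

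Of the luminal markers 12 rose, among them the secretory genes Tgm4 and Pbsn, and 5 fell, among them Krt8, Krt18, Cdh1 and Cldn3. As a list they had a camera adjusted p of 0.0699. A larger share of luminal cells or of their RNA in the Pten_p65KO sorts is a candidate explanation for the rises. For Egf and other large rises outside the list this was not tested. One common factor for the luminal markers that rose would give them like folds, but their log2 fold changes ran from 0.53 to 7.74 with an SD of 2.10, against a median standard error of 0.39. That spread decides nothing, because cells of the main population may hold some of these RNAs already. The median log2 ratio of replicate 2 to replicate 1 over the same 12 markers was 1.28 in Pten and 0.32 in Pten_p65KO. A change of state in the cells and a mixed sort cannot be told apart, because single-cell values are missing. The effect of p65 loss is among the open explanations, as is the Pten allele, which the values do not check.

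Class I genes of the H2 complex fell, which may come from another H2 haplotype in one group, since reads of a variant allele can align less well. Of the H2 genes on chromosome 17, 14 of 23 were called lower and 1, H2-Eb1, higher, and for these strain and the loss of p65, which the design names, cannot be told apart without sequence reads. All 7 class I presentation genes outside chromosome 17, whose reads such a haplotype does not alter, were lower, 3 of them called, with a median of -0.61. A strain difference may also lie behind large changes elsewhere, and was not tested there. Picked after their values were seen were 8030451A03Rik, at 602 and 458 in Pten and 0 and 0 in Pten_p65KO, and 6820402A03Rik, at 0 and 0 against 372 and 467. However, 8030451A03Rik (chromosome 4, 63979854 to 64149924) overlaps Tnc (63959785 to 64047015) on the other strand. Tnc fell 114-fold and the strand setting is not stated, so the fall of 8030451A03Rik may not be separate from that of Tnc. In the window of chromosome 19 that holds Rela, up to 20 Mb, 56 of 275 tested genes were called (20.4%), against 25.3% elsewhere (Fisher's exact test p = 0.0686).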
